A study of Mus musculus with 9 samples.

How the data were processed

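The RNA of fully grown oocytes from 3 groups (WT, MG and MZ, 3 libraries each) was amplified by the Smart-seq2 procedure and made into libraries with the NEBNext Ultra RNA kit, per the labels' protocols. Sequencing was paired-end with 150 bp reads, per the series design. Per the submitters' processing notes and the design text, the authors trimmed the reads, aligned them to mm10 with TopHat2 2.0.13, and computed FPKM with Cufflinks 2.2.1. The deposited values are FPKM (fragments normalized by the authors for transcript length and library size) for each gene and library. The deposited table also holds the authors' log2 fold change, p-value and q-value for each pair of groups, which the authors computed with Cuffdiff at default settings per the design text. The fold changes in the deposited table give the group named later over the group named first, and minus infinity is stored there as a spreadsheet error. How strand was treated in counting is not given in the sources used here.

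The table has 24255 rows. In 27 rows the gene symbol had been turned into a date, and these were left out, which leaves 24228. Symbols were matched to GENCODE M21 (GRCm38), with 23105 (95.4%) matched, and coordinates are given from that annotation, 1-based. Of the rows, 5705 share a locus with another row, so reads of overlapping genes may be split. For most genes with a mean FPKM of at least 1 the deposited p-value is 1 (7464 of 10981 for MG against WT).

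FPKM are not counts, so no count model was used. The number of fragments per library was estimated from the lowest FPKM values of 2220 genes with 1 transcript of at least 1500 bp, since 1 fragment gives a value that depends on the length of the transcript. Between 76.9% and 86.7% of the low values lay within 15% of the value of 1 fragment. The libraries were put at 813700, 653200 and 689900 fragments in WT, 579000, 708400 and 867100 in MG, and 676600, 1040900 and 843500 in MZ. Fragment numbers of genes are approximate, because they use the longest annotated transcript. Reads amplified without molecular identifiers are not independent molecules, so any test on fragments covers counting error only.

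Genes with FPKM of at least 1 in at least 3 of the 9 libraries were tested (10801 genes). The values were taken as log2(FPKM + 1) and fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend of the variance on the mean level), with all 9 libraries in 1 fit and 6 residual degrees of freedom. The 3 contrasts were MG against WT, MZ against WT and MG against MZ. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg within each contrast, and the threshold was an adjusted p under 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. An FPKM of 0 can be a failed estimate, so such genes are described as listed at 0.

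Before the data were examined, 31 gene lists were fixed, covering mTOR signalling, translation, oocyte function, meiosis, metabolism, stress, chromatin, and markers of other ovarian cells. The 30 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, beside camera with an estimated correlation and fry. The list of mitochondrially encoded transcripts was not analysed here, since its genes have no rows. Genes named in the text were chosen by a rule also fixed in advance. It takes Mtor, Gdf9 and Zp3 and, per comparison, up to 8 genes per direction with the most extreme log2 fold change among those that passed, had no overlap between the groups and reached a mean of 5 FPKM in the higher group, leaving out clone names. Where fewer than 3 qualified, the 5 with the smallest p were taken as not passing. For each list it takes up to 2 rising and 2 falling members that passed, or, where the list passed and its members did not, up to 2 members with the smallest p. For the overlap it takes up to 6 genes per direction called in both. Some genes that this rule takes are not reported here.

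The steps were tested on simulated data, with fragments drawn from the levels and depths of these libraries and 200 genes changed in MG. For MG against WT, with 9962 simulated genes tested, 56 of 95 genes changed 4-fold and 8 of 99 genes changed 2-fold were recovered, and 8 unchanged genes were called. For MZ against WT, where no gene was changed, 0 of 9962 genes were called. Camera called 0 of 30 lists in each simulated comparison, and called the proteasome list with an adjusted p of 2.3e-12 when its members were lowered 1.5-fold in MG. Simulated genes vary independently, which real genes of a list need not do.

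Alternatives covered the pseudocount, the filter, the scaling, the variance model, the libraries in the fit, a block for the replicate number and leaving out each library. Other alternatives were chosen after seeing the data, namely a filter of 5 approximate fragments, a variance trend on approximate fragments, removal of trends with transcript length or mean level, and scaling of each library to the same FPKM sum. Distances between libraries, and library sums, were tested by exact permutation. Unchanged groups and the WT libraries they share were simulated 100 times, from the fitted WT means and residual SDs.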

Results

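Gene expression was measured by RNA sequencing in fully grown mouse oocytes at the germinal vesicle stage, the stage of prophase arrest before meiosis resumes. The oocytes came from large antral follicles of females primed with 5 IU of PMSG, a gonadotropin that promotes follicle growth, 46 h before collection. The 3 groups were wild type (WT), oocytes in which the floxed Mtor gene was targeted by Cre under the Gdf9 promoter (MG), and oocytes in which it was targeted by Cre under the Zp3 promoter (MZ). Gdf9 and Zp3 are oocyte genes, and Gdf9-Cre acts from an earlier stage of follicle growth than Zp3-Cre. Mtor encodes the kinase of the mTOR complexes, which control translation and cell growth. Each group had 3 libraries. Nothing in the labels says that these came from separate animals, so p-values measure the spread between these libraries, which may be technical. The age is given as 23 days in the series design and as 6 months in the sample labels, and this was not resolved.

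The deposited values are FPKM per gene and library. From the steps between low FPKM values, the libraries were estimated to hold between 579000 fragments (MG 1) and 1040900 fragments (MZ 2). This estimate rests on annotated transcript lengths and is approximate. In a 1 kb transcript 1 fragment was worth between 1.308 FPKM (MG 3) and 2.367 FPKM (MG 1), so a gene of a few FPKM rests on a handful of fragments. FPKM above 0 was listed for between 10670 genes (MZ 1) and 12097 genes (MG 3). The FPKM values of a library summed to 498936 ± 64355 in MG (SD, n = 3), 652537 ± 67110 in WT (SD, n = 3) and 670216 ± 10778 in MZ (SD, n = 3). The lowest sum, 428329, was in MG 3. The MG sums lay below all WT and all MZ sums (exact permutation test, two-sided, p = 0.1 for each, the smallest p that 3 against 3 libraries allow). After filtering, 10801 genes were tested in all 3 comparisons.

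Mtor itself (chromosome 4, 148448611 to 148557683, GRCm38, protein coding) was measured first. Its FPKM was 3.18 ± 0.20 in WT, 5.29 ± 0.68 in the libraries labelled MG and 5.21 ± 1.18 in the libraries labelled MZ (SD, n = 3 each). All 3 MG and all 3 MZ values were above all 3 WT values. The log2 fold change was 0.59 for MG against WT (limma adjusted p = 0.36) and 0.56 for MZ against WT (limma adjusted p = 0.80), so neither passed the threshold. About 38 fragments in WT, 77 in MG and 71 in MZ lie behind these means. The FPKM of a whole gene also counts reads from exons outside the deleted part, and the locus overlaps another gene in the table, so the value does not check the deletion, and MG and MZ stand throughout for the libraries labelled so. Gdf9 (16680 ± 1115 FPKM in WT, 13560 ± 5665 in MG, 17820 ± 648 in MZ; SD, n = 3 each) and Zp3 (1194 ± 130, 1015 ± 428 and 1470 ± 73.3 FPKM in the same order) did not pass in any comparison. The lowest Gdf9 and Zp3 values, 7327 and 555 FPKM, were both in MG 3.

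**Figure D1:**
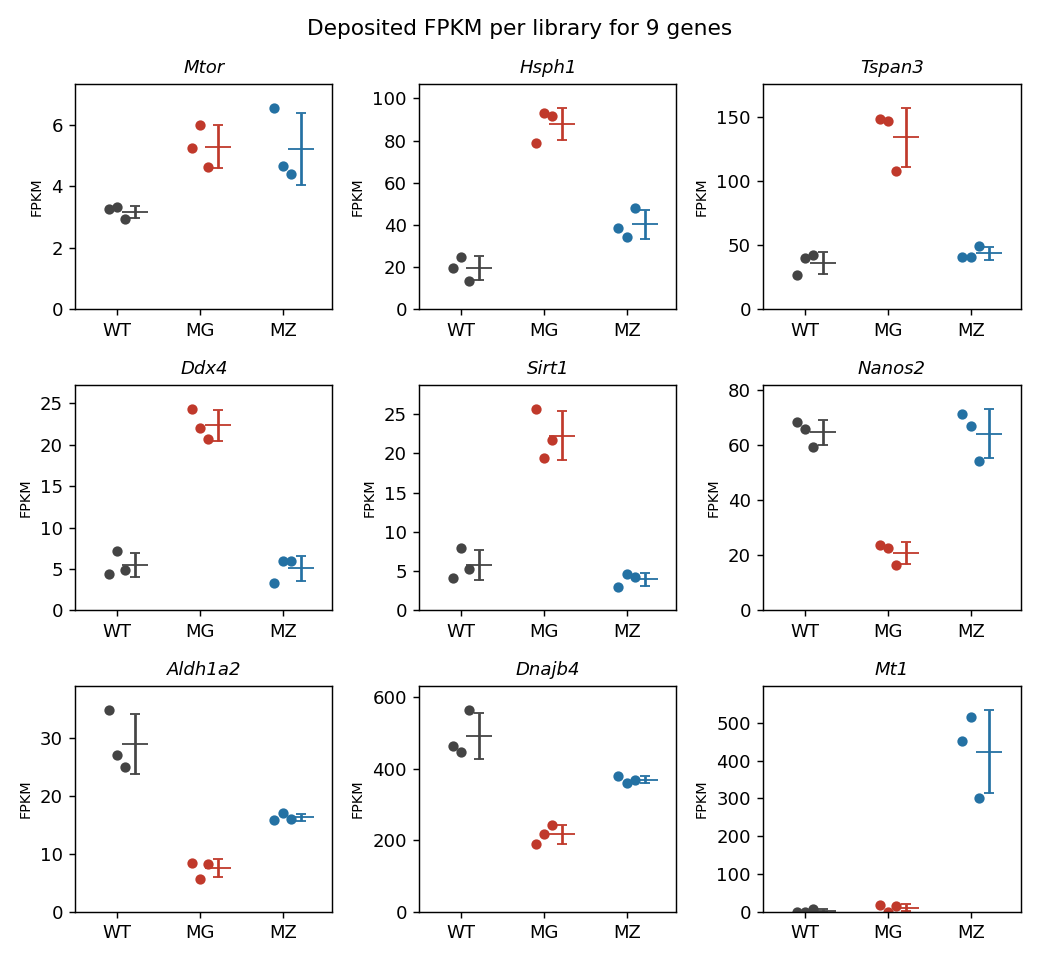
Deposited FPKM of 9 genes (vertical axes, linear, from 0) in the 3 WT, 3 MG and 3 MZ libraries, with points for single libraries and a bar for the mean ± SD. Mtor was higher in all MG and MZ libraries than in WT without passing the test, while Hsph1 averaged 87.9 FPKM in MG and Mt1 averaged 424 FPKM in MZ.

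The libraries were compared as wholes to ask whether they group by genotype. Over the 1336 most variable genes, the mean distance (1 minus Pearson r, across genes) was 0.497 within groups and 0.556 between groups. The difference of -0.059 was the lowest of the 280 assignments of the libraries to groups (exact permutation test, one-sided, p = 0.0036, the smallest they can give). Without MZ 1 the difference was -0.041 and the exact p was 0.057. A division into 2 clusters placed the 3 MG libraries apart from the 3 WT and 3 MZ libraries, and a division into 3 clusters parted MG 1 from MG 2 and MG 3 while WT and MZ stayed together. The first principal component, with 19.7% of the variance, also set MG apart. Each WT library was nearest to MZ 2, not to another WT library, and MG 1 was nearest to MZ 3.

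**Figure D2:**
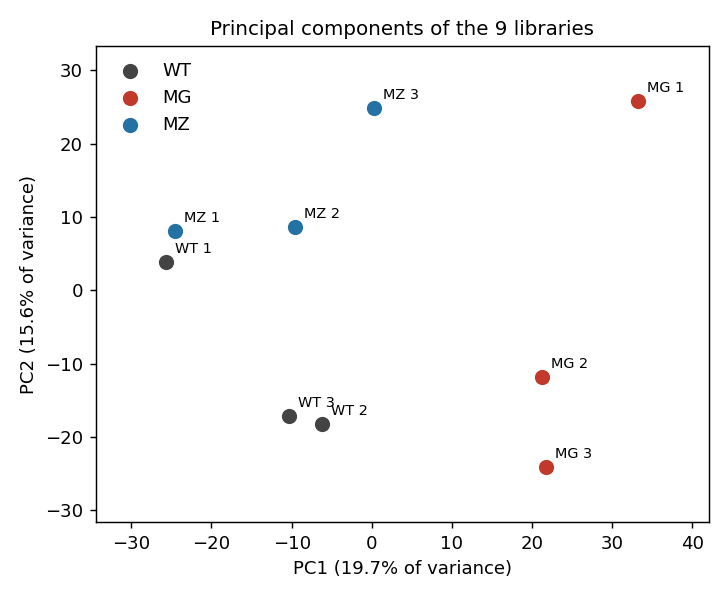
First and second principal components (axes, with the percent of variance) of log2(FPKM + 1) over the 1336 most variable genes; each point is 1 of the 9 libraries, coloured by group. The 3 MG libraries lie at 21.2 to 33.2 on the first component and the other 6 libraries at 0.291 or below.

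The comparison of MG with WT asks how targeting Mtor by Gdf9-Cre altered the transcript pool of the fully grown oocyte. Hsph1, a chaperone of the heat shock protein 110 family, rose from 19.4 ± 5.68 FPKM in WT to 87.9 ± 7.67 in MG (SD, n = 3 each). Tspan3, a tetraspanin membrane protein, rose from 36.4 ± 8.74 to 134.5 ± 22.9 FPKM. Ddx4, the germ-cell RNA helicase of the vasa family, rose from 5.48 ± 1.48 to 22.3 ± 1.84 FPKM. Sirt1, an NAD-dependent deacetylase, rose from 5.78 ± 1.95 to 22.3 ± 3.17 FPKM. Nanos2, a germ-cell RNA-binding protein, fell from 64.5 ± 4.62 to 20.9 ± 4.02 FPKM, and Aldh1a2, an enzyme of retinoic acid synthesis, fell from 28.9 ± 5.18 to 7.48 ± 1.53 FPKM.

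In all, 37 genes passed the limma test (20 higher and 17 lower in MG). For each of the 37 the 3 MG values did not overlap the 3 WT values. Over all tested genes 21.4% showed no such overlap, where chance gives 10%. An unadjusted p under 0.05 was found for 1917 genes, against 540 expected by chance. Hsph1 had a log2 fold change of 2.16 ± 0.24 (SE, limma adjusted p = 0.013). Tgif1, a homeobox repressor, had 3.79 ± 0.52 (adjusted p = 0.018 by limma) and a WT mean of 1.87 FPKM, which is about 8 fragments over the 3 libraries. Zfp707, a zinc finger gene, rose from 3.88 ± 1.42 to 34.3 ± 9.10 FPKM. Tceb3, an elongin gene, rose from 1.96 ± 0.71 to 11.6 ± 2.10 FPKM. Tmem205, Phpt1 and Olfr513 were listed at 0 in all 3 WT libraries and had means of 12.6, 9.57 and 5.24 FPKM in MG. Tmem205 overlaps another gene in the table, so its reads may be split.

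Among the genes that fell, Dnajb4, a co-chaperone of the heat shock protein 40 family, went from 490.7 ± 63.2 to 215.9 ± 26.6 FPKM. Brdt, a bromodomain protein of germ cells, went from 302.7 ± 22.8 to 137.8 ± 22.1 FPKM. Tmem171 went from 70.1 ± 21.2 to 11.4 ± 6.81 FPKM, and Stard5, a lipid transfer protein, from 26.5 ± 5.45 to 9.29 ± 0.92 FPKM. Cyp2c53-ps, a transcribed pseudogene, had 17.3 ± 4.63 FPKM in WT and was listed at 0 in all 3 MG libraries. Its reads could be shared with related Cyp2c genes.

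Of the 30 tested gene lists 5 were lower in MG by camera with its preset correlation. Of 36 proteasome subunits 30 had negative and 6 positive log2 fold changes (median -0.37, camera adjusted p = 0.00069). No proteasome gene passed over all genes, and 4 passed as lower when adjusted over the list alone. Psma7 had 71.5 ± 5.29 FPKM in WT and 30.4 ± 11.5 in MG, and Psmb7 72.4 ± 12.5 and 36.1 ± 11.4. With an estimated correlation the proteasome list did not pass (adjusted p = 0.32).

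Nuclear-encoded genes of oxidative phosphorylation had a median of -0.40, with 55 of 72 negative (camera adjusted p = 0.0026; adjusted p = 0.64 with an estimated correlation). Ndufb9 had 66.5 ± 13.1 FPKM in WT and 23.5 ± 5.48 in MG, and Ndufb10 had 15.2 ± 6.75 and 2.06 ± 3.58. Neither passed over all genes, and 0 members of the list passed when adjusted over the list alone. Cytosolic ribosomal protein genes had a median of -0.44, with 48 of 62 negative (camera adjusted p = 0.0044; adjusted p = 0.64 with an estimated correlation). Rpl39 had 371.1 ± 153.5 FPKM in WT and 152.6 ± 44.0 in MG, and there were 0 members passing over all genes or adjusted over the list alone. Ribosomal protein genes have many processed pseudogenes that can share their reads, and the locus of Rpl39 overlaps other genes.

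Maternal-effect genes, whose products support the early embryo, had a median of -0.31, with 32 of 47 negative (camera adjusted p = 0.0032; adjusted p = 0.64 with an estimated correlation). Mbd3l2 fell from 218.2 ± 37.1 to 102.1 ± 21.3 FPKM and was the 1 member that passed over all genes; adjusted over the list alone, 5 were lower and 1 higher. Zar1l had 637.5 ± 49.8 FPKM in WT and 344.2 ± 130.3 in MG. Kdm1b, a histone H3K4 demethylase needed for maternal imprints, had 55.4 ± 18.8 and 115.9 ± 22.03 and did not pass over all genes. Histone genes had a median of -0.44, with 19 of 29 negative (camera adjusted p = 0.0043; adjusted p = 0.24 with an estimated correlation). Hist1h2bc fell from 406 ± 31.6 to 221.2 ± 17.02 FPKM, and 8 histone genes were lower when adjusted over the list alone. Histone genes are near-identical copies, and their values are uncertain for that reason. As a share of the FPKM sum these lists differed between the groups by less than the larger of the group SDs, with 0.264 ± 0.016% in WT and 0.275 ± 0.012% in MG for the proteasome, 0.831 ± 0.035% and 0.852 ± 0.054% for oxidative phosphorylation, 0.475 ± 0.131% and 0.427 ± 0.095% for ribosomal proteins, 11.4 ± 0.28% and 10.4 ± 1.29% for maternal-effect genes, and 2.09 ± 0.23% and 2.07 ± 0.19% for histones (SD, n = 3 each). With each library scaled to the same FPKM sum, a setting chosen after seeing the data, their medians were 0.01, -0.03, -0.09, 0.08 and -0.05 in the same order, and the median of all tested genes was 0.36. Camera compares a list with the other genes, so a shift shared by all genes largely cancels in it. Its calls of all 5 as lower there (adjusted p = 0.00024 to 0.047) therefore do not test the scaling. For all 5 lists the median of single libraries (log2 against the WT mean) was lowest in MG 3, the library with the lowest FPKM sum. Without MG 3, 2 of the 5 lists passed (proteasome and histones). In MG 1 the medians of ribosomal proteins (0.16), oxidative phosphorylation (0.008) and maternal-effect genes (-0.088) lay within the range of the WT libraries. Those of the proteasome (-0.29) and histones (-0.35) in MG 1 lay below all WT libraries.

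Other lists held single genes that passed. Of the genes for storage and decay of maternal mRNA, Ythdf2, a reader of N6-methyladenosine, rose from 33.2 ± 5.80 to 83.4 ± 15.2 FPKM, and Cnot7, a deadenylase subunit, fell from 382.6 ± 50.2 to 194.4 ± 16.6 FPKM. The loci of Cnot7 and of Nusap1 overlap other genes. Nusap1, a spindle protein, fell from 192.9 ± 33.2 to 95.5 ± 9.63 FPKM. Of 48 tested mTOR signalling components 0 passed over all genes, and the list had camera adjusted p = 0.91 with a median of 0.18 and a test direction of lower. Granulosa and cumulus cell markers (16 tested) had a median of 0.06 and camera adjusted p = 0.91.

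The count for MG against WT was sensitive to single libraries. It was 5, 9 and 3 genes without WT 1, WT 2 or WT 3, 6 and 23 without MG 2 or MG 3, and 10, 10 and 12 without MZ 1, MZ 2 or MZ 3, compared with 32 without MG 1. Hsph1 passed in each alternative fit run except the test against a 1.5-fold change (treat adjusted p = 0.078, range 0.0045 to 0.078 over its 25 alternatives). Other calls were lost in more than 12 of their alternatives, namely those of Mbd3l2 in 20 of 25, of Cnot7, Hist1h2bc, Nusap1 and Sirt1 in 17 of 25, of Stard5 in 16 of 25, of Ythdf2 in 14 of 25, of Ddx4 in 13 of 25, of Tceb3 in 13 of 24 and of Olfr513 in 13 of 23. With upper quartile scaling the calls were 20 higher and 10 lower, with quantile normalization 16 higher and 5 lower, and with each library scaled to the same FPKM sum 61 higher and 5 lower. The authors' deposited table lists 446 genes with q under 0.05 for this pair of groups (117 higher and 329 lower in MG), and 26 of the 37 genes are among them.

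**Figure D3:**
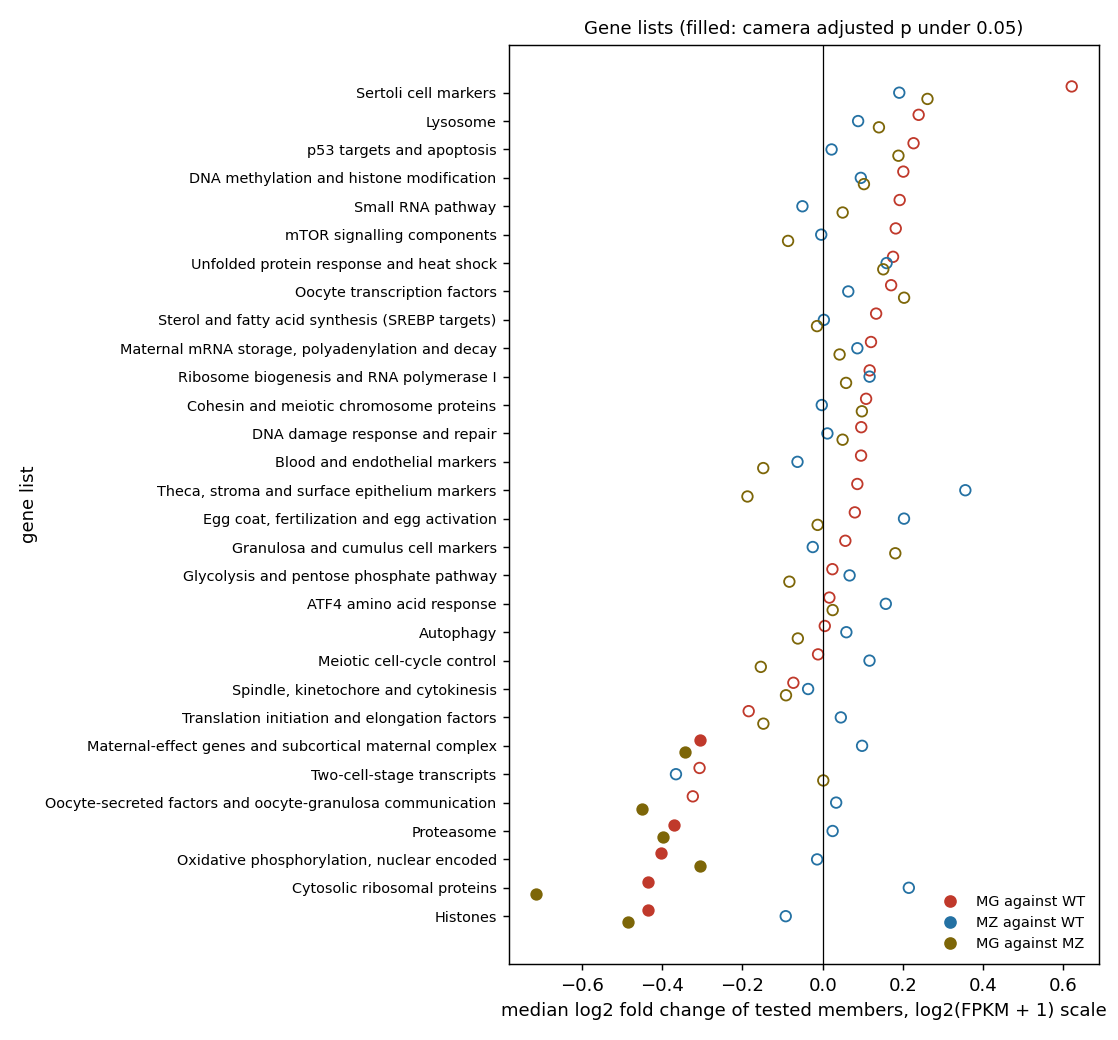
Median log2 fold change (horizontal axis, log2(FPKM + 1) scale) of the tested members of 30 gene lists (vertical axis) in the 3 comparisons, with filled points where the camera adjusted p with preset correlation was under 0.05. The 5 filled lists of MG against WT have medians from -0.44 to -0.31, and no list is filled for MZ against WT. With an estimated correlation no list passed, with quantile normalization the camera direction of the maternal-effect list turned, and with each library scaled to the same FPKM sum the medians of the 5 lists were -0.09 to 0.08.

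The comparison of MZ with WT asks the same of Zp3-Cre. Mt1, a metallothionein that binds zinc and copper, was listed at 0, 0 and 8.26 FPKM in WT and at 452.8, 516.1 and 302.1 FPKM in MZ, with a mean of 10.3 ± 9.07 FPKM in MG (SD, n = 3). Its log2 fold change was 7.62 ± 1.07 (SE, limma adjusted p = 0.0495). Cox8c, a germ-cell isoform of a cytochrome c oxidase subunit, was listed at 0 in all WT and MG libraries and at 9.03 ± 1.82 FPKM in MZ, which is about 7 fragments (limma adjusted p = 0.017). Cyp2c53-ps fell from 17.3 ± 4.63 to 0.99 ± 0.92 FPKM (limma adjusted p = 0.0495). The remaining gene, 1700069L16Rik, lies outside the naming rule and was picked after its values were seen; it was listed at 0 in WT and at 5.19 ± 1.23 FPKM in MZ, about 6 fragments.

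Thus 4 of 10801 genes passed by limma (3 higher and 1 lower in MZ), with 680 genes at an unadjusted p under 0.05 against 540 expected by chance. No overlap between the 3 MZ and the 3 WT values was found for 12.2% of genes, where chance gives 10%. Genes with small p that did not pass included Zc3h6 (227.2 ± 67.5 FPKM in WT, 92.5 ± 3.45 in MZ), Ceacam10 (20.7 ± 3.82 and 6.54 ± 1.98), Uchl4 (38.5 ± 6.82 and 15.7 ± 3.42) and Pts (13.97 ± 1.87 and 2.87 ± 0.68). Phpt1, Tmem205 and Snf8 were listed at 0 in WT and at 7.71, 7.03 and 4.77 FPKM in MZ, and did not pass either. The list of mTOR signalling components had camera adjusted p = 0.89. None of the 30 lists passed. The smallest camera adjusted p was 0.12, for cytosolic ribosomal protein genes (median 0.21, 37 of 62 positive) and for two-cell-stage transcripts (median -0.37, 9 of 12 negative).

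The call of Mt1 was lost in 18 of its 25 alternative fits, and its adjusted p ranged from 0.010 to 0.71. The count was 1, 3 and 0 genes without WT 1, WT 2 or WT 3, 6, 2 and 1 without MG 1, MG 2 or MG 3, and 0 without any 1 of the MZ libraries. The call of Cyp2c53-ps was lost in 20 of 24 (adjusted p 0.046 to 0.76). With quantile normalization, and with scaling to the same FPKM sum, 1 gene was higher and 0 lower. The authors' deposited table lists 85 genes with q under 0.05 (29 higher and 56 lower in MZ), and 0 of the 4 genes are among them.

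MG was then compared with MZ directly, which tests whether the effects of the 2 Cre lines differ. Sirt1 (22.3 ± 3.17 FPKM in MG, 3.96 ± 0.85 in MZ), Ddx4 (22.3 ± 1.84 and 5.10 ± 1.51), Zfp707 (34.3 ± 9.10 and 5.16 ± 2.10) and Tspan3 (134.5 ± 22.9 and 43.9 ± 5.19) were higher in MG. Ccne2, cyclin E2, was also higher (27.5 ± 1.40 and 7.37 ± 1.00), as was Uchl4 (54.3 ± 6.11 and 15.7 ± 3.42). The loci of Ccne2 and Uchl4 overlap other genes. Zfand1 and Olfr513 were listed at 0 in all MZ libraries and averaged 6.07 and 5.24 FPKM in MG. Nanos2 (20.9 ± 4.02 and 64.0 ± 8.95), Hmgb2, a chromatin protein (79.5 ± 21.1 and 227.8 ± 23.5), B4galt4, a galactosyltransferase (105.8 ± 8.90 and 238.6 ± 12.6), and Ndufb3, a complex I subunit (52.3 ± 8.79 and 137.5 ± 27.2), were lower in MG.

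In all, 14 genes passed by limma (8 higher and 6 lower in MG), with 1906 genes at an unadjusted p under 0.05 and 25.2% of genes without overlap, where chance gives 10%. Of 30 lists 6 passed camera, each lower in MG. Cytosolic ribosomal protein genes had a median of -0.71, with 53 of 62 negative (camera adjusted p = 3.6e-06; adjusted p = 0.38 with an estimated correlation), and 4 of them passed as lower when adjusted over the list alone. Fau had 14.7 ± 5.54 FPKM in MG and 45.9 ± 11.1 in MZ. Proteasome genes had a median of -0.40 (29 of 36 negative, camera adjusted p = 0.00016; adjusted p = 0.27 with an estimated correlation). Psma4 had 35.8 ± 2.45 FPKM in MG and 70.9 ± 1.84 in MZ. Maternal-effect genes had a median of -0.34 (35 of 47 negative, camera adjusted p = 0.0005; adjusted p = 0.45 with an estimated correlation), and adjusted over the list alone 15 were lower and 4 higher. Oog2 had 423.8 ± 129.7 FPKM in MG and 969.3 ± 153.7 in MZ, and Pou5f1 33.5 ± 6.30 and 91.4 ± 16.3. Oxidative phosphorylation genes had a median of -0.31 (52 of 72 negative, camera adjusted p = 0.0016; adjusted p = 0.43 with an estimated correlation). Histone genes had a median of -0.48 (19 of 29 negative, camera adjusted p = 0.010; adjusted p = 0.27 with an estimated correlation). Oocyte-secreted factors and genes of oocyte to granulosa communication had a median of -0.45 (13 of 21 negative, camera adjusted p = 0.047; adjusted p = 0.38 with an estimated correlation). This call was lost in 14 of 22 alternative settings, among them both other pseudocounts and no filter (median -0.53 to -0.05, adjusted p 0.013 to 0.62). Scaled to the same FPKM sum, the 6 lists had medians of -0.35, 0.03, 0.05, 0.09, -0.07 and -0.05 in the order given, and the median of all genes was 0.39. Camera called the first 5 lists as lower than the other genes, a comparison in which a shift shared by all genes largely cancels. Gja4, the connexin of oocyte gap junctions, had 643.8 ± 334.3 FPKM in MG and 1936 ± 68.9 in MZ, and 5 of these genes were lower when adjusted over the list alone.

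The count was 213, 9 and 1 genes without WT 1, WT 2 or WT 3, 210, 3 and 3 without MG 1, MG 2 or MG 3, and 0 without any 1 of the MZ libraries. The call of Ndufb3 was lost in 13 of 25 alternatives. Calls of Ddx4, Tspan3, Hmgb2 and Zfp707 were lost in 11 of 25 and that of Olfr513 in 11 of 23. B4galt4 lost its call in 9 of 25, Sirt1 in 8 of 25, Zfand1 in 8 of 24, and Ccne2, Uchl4 and Nanos2 in 7 of 25. With quantile normalization 9 genes were higher and 4 lower, with scaling to the same FPKM sum 25 were higher and 6 lower, and with the 6 libraries of the 2 groups alone 73 genes passed. The authors' deposited table lists 977 genes with q under 0.05 (306 higher and 671 lower in MG), and 9 of the 14 genes are among them.

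Both effects were set against each other to ask whether they share genes. Cyp2c53-ps, lower in both, was the 1 gene called in both comparisons with WT. Independent lists would share 0.0016 lower genes, and unchanged groups simulated with shared, redrawn WT libraries shared 0 called genes on average. The overlap of 1 gene was not tested further. An unadjusted p under 0.05 with the same sign in both was found for 216 genes. Unchanged groups simulated with shared, redrawn WT libraries gave 118 such genes on average and at most 149, and independent lists would give 60.8. The correlation of log2 fold changes across genes, which are not independent replicates, was 0.41, compared with 0.50 in the simulation. Their covariance was 0.152, compared with 0.108 on average and at most 0.118 in 100 simulated sets. The shared WT libraries, which were too few to split, raise such overlap, since the simulated groups held no effect. The simulation redraws the shared WT libraries from the fitted WT means and residual SDs, and holds no effects. MG against WT had 1917 genes at an unadjusted p under 0.05 by limma, with 540 expected by chance. The simulated 118 may thus be too low a baseline, and the excess of the 216 genes over it is not read as shared effects. The SDs of single genes carry no correlation between genes, so the highest simulated values, 149 and 0.118, may be too low. The excess of the covariance is not read as shared effects either.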

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

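The tests of Mt1 in the third pattern were chosen after its result was seen; the corrections for transcript length and mean level and the scaling to the same FPKM sum were added after seeing the data. MG and MZ differed under a direct test in 14 genes and in 6 gene lists. The median log2 fold changes of the lists, MG against MZ, were -0.71 for cytosolic ribosomal proteins, -0.45 for oocyte-secreted factors, -0.34 for maternal-effect genes, -0.31 for oxidative phosphorylation, -0.40 for proteasome and -0.48 for histones. These came from camera with a preset correlation, and all 6 calls were lost with an estimated correlation (smallest adjusted p = 0.27).

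For MG against WT, 37 genes passed, and the highest of the other 9 splits of the 6 libraries gave 3; 1 of 10 splits gave as many. For MG against MZ, 14 genes passed and the highest other split gave 2, again with 1 of 10 splits as large. For MZ against WT, 4 genes passed while another split gave 6, and 2 of 10 splits gave as many. The count for MZ against WT thus did not set the grouping by genotype apart from other splits. With 10 splits a share under 0.05 cannot be reached.

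The first pattern is the lower level of lists of abundant transcripts in MG against WT. With each library scaled to the same FPKM sum the 5 medians were -0.09 to 0.08. Camera compares a list with the other genes, so a shift shared by all genes largely cancels in it. It called all 5 as lower there, which is no test of the scaling. With quantile normalization, of the 5 lists camera called only ribosomal proteins and proteasome as lower (adjusted p = 0.023 each). With an estimated correlation no list passed. RNA of granulosa cells at such a bound is argued against, since 0 of 7 granulosa genes reached 10 FPKM with a doubling in MG. The highest, Inha, averaged 1.72 FPKM in WT and 4.85 in MG. Amh, Cyp11a1 and Hsd17b1 were at 0 in WT and averaged 0.51, 0.26 and 0.38 FPKM in MG. Fshr was lower in MG (2.25 and 1.27 FPKM), Gja1 was at 0.91 in both and Foxl2 at 0. A smaller amount of granulosa RNA is not excluded. RNA of other ovarian cells was not tested this way. For theca, stroma and surface epithelium, the median marker level (log2 against the WT mean) was 1.07, -0.22 and -0.29 in MG 1 to 3. It was -0.39, 0.29 and 1.28 in MZ 1 to 3. For blood and endothelium it was 0.59, -0.26 and -0.51 in MG 1 to 3, and -0.51, 0.04 and 0.65 in MZ 1 to 3. After the trend with transcript length was removed, 2 of the 5 lists passed, proteasome (median from -0.37, SD of members 0.43, to -0.29, SD 0.44) and maternal-effect genes (from -0.31, SD 0.55, to -0.27, SD 0.49), while the medians of the 3 that no longer passed shrank, ribosomal from -0.44 (SD 0.71) to -0.21 (SD 0.70), oxidative phosphorylation from -0.40 (SD 0.87) to -0.22 (SD 0.85) and histones from -0.44 (SD 1.43) to -0.27 (SD 1.40). After the trend with mean level was removed, 2 passed, ribosomal (-0.41, SD 0.73) and proteasome (-0.26, SD 0.44); maternal-effect genes went to -0.02 (SD 0.46) and oxidative phosphorylation to -0.24 (SD 0.89), and histones went from -0.44 (SD 1.43) to -0.36 (SD 1.43) and missed the threshold (camera adjusted p = 0.069), for a cause that was not tested. Without library MG 3 also 2 passed, proteasome (-0.29, SD 0.46) and histones (-0.41, SD 1.53), with -0.15 (SD 0.89) for ribosomal, -0.21 (SD 0.48) for maternal-effect and -0.22 (SD 0.96) for oxidative phosphorylation genes. Each of these 3 may thus account for part of the pattern, and they cannot be told apart from an effect of the genotype. As many lists, 5, passed in 3 of the 10 splits of the 6 libraries, the grouping by genotype among them. The number of passing lists thus did not set the grouping by genotype apart from other splits. The highest of the other splits also gave 5, and 10 splits are too few for a share under 0.05.

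The second pattern is the higher Mtor level in the libraries labelled MG and MZ, which did not pass the limma test. For Mtor, 147 of 185 approximate fragments (79.5%) were in the 6 libraries labelled MG or MZ, which hold 68.6% of all fragments. This argues against counting error of independent fragments (exact binomial test, two-sided, p = 0.0011, counting error only). Reads amplified without molecular identifiers are not independent molecules. The test therefore does not cover the sampling of few molecules, which stays open. A chromosome segment carried along with the floxed allele may alter levels of genes on it; 4 of 128 tested genes within 10 Mb changed alike in both (3.12%, exact 95% limits 0.858% to 7.81%), compared with 1.98% of other genes (Fisher's exact test, one-sided, p = 0.25), which leaves this open. Reads from exons outside the deleted part also stay open, since 0 exon-level values were among the files used. An effect of the genotype on the transcript level stays open as well and was not tested.

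The third pattern is Mt1, higher in all MZ libraries than in any WT or MG library. It was listed at 17.1, 0 and 13.7 FPKM in MG 1 to 3, and was not among the genes that passed for MG against MZ. A metal response would raise Mt2 and Slc30a1 too, and the log2 change of Mt2 in MZ was 1.34, below the bound of 1.91 set from the change of Mt1 (7.62), while Slc30a1 was at -0.35. In 1 MZ library Mt2 reached 4.01 on about 5 fragments, so its spread spans the bound and this test decides nothing. Mt1 rested on about 755 fragments in MZ. A transcribed transgene that carries part of Mt1 could give such a value; 0 values on the position of reads along Mt1 were among the files used, and this cannot be told apart from an effect of the genotype.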

How the results depend on the processing

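Settings based on approximate fragments, on removed trends or on the FPKM sum were chosen after seeing the data; all others were fixed before the data were examined. Mtor kept its direction and stayed short of the threshold against WT under each alternative run, with log2 fold changes of 0.40 to 0.91 for MG (0.51 to 0.66 without single libraries) and 0.41 to 0.69 for MZ (0.41 to 0.65 without single libraries), and adjusted p of 0.16 to 1 and 0.66 to 1. The distance within groups stayed below that between groups in each setting run, with a difference of -0.013 over all 10801 tested genes (0.079 within and 0.092 between), of -0.061 with Spearman and -0.052 with pseudocount 0.1, and of -0.071 to -0.041 without single libraries (exact p = 0.057 without MZ 1). The counts of genes past the threshold moved more. For MG against WT (37 genes) they were 17 with no filter, 23 with a maximum FPKM of at least 1, 21 with quantile normalization, 66 with the same FPKM sum, 84 with array weights, 1 against a 1.5-fold threshold (treat), 67 with a filter of 5 approximate fragments, 63 with the spread modelled on approximate fragments, 5 with the 2 groups alone and 446 in the authors' deposited table. Leaving out single libraries gave 3 to 32 genes. For MZ against WT (4 genes) they were 2 with pseudocount 0.1, 2 with no filter, 0 with FPKM of at least 5, 1 each with quantile normalization, the same FPKM sum, robust eBayes, array weights and the spread modelled on approximate fragments, 0 with treat, 0 with the fragment filter and 85 in the authors' deposited table. Leaving out single libraries gave 0 to 6 genes. For MG against MZ (14 genes) they were 6 and 5 with pseudocounts 0.1 and 0.01, 9 with no filter, 31 with the same FPKM sum, 791 with array weights, 0 with treat, 71 with the fragment filter, 77 with the spread modelled on approximate fragments, 73 with the 2 groups alone and 977 in the authors' deposited table. Leaving out single libraries gave 0 to 213 genes. The cause of these shifts was not tested.

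The residuals gave no sign that the replicate numbers pair the libraries. Residuals of the 9 pairs with the same number correlated at -0.070 to 0.073 (mean 0.0019), and not every library correlated best with its own number. The labels do not say whether libraries with the same number share an animal or day, and these correlations cannot exclude it. With the replicate block 13, 0 and 159 genes passed for MG against WT, MZ against WT and MG against MZ, and 0 genes were shared by the comparisons with WT. That overlap, 1 gene in the main setting, was 2 and 4 genes with pseudocounts 0.1 and 0.01, 0 with no filter, with FPKM of at least 5, with quantile normalization, with the same FPKM sum and with the fragment filter, and 0 to 2 without single libraries.

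Of the 5 lists of MG against WT, 0 passed with an estimated correlation or fry. The number passing was 3 with FPKM of at least 5, 3 with quantile normalization (1 of them higher, the unfolded protein response and heat shock), 2 with the length trend removed, 3 with the level trend removed (again 1 higher) and 3 to 5 without single libraries (3 without MG 3, of which 1 was higher, the same heat shock list). For MZ against WT it was 2 with a maximum FPKM of at least 1, 1 with the fragment filter and 0 to 1 without single libraries. For MG against MZ it was 0 with an estimated correlation or fry, 2 with quantile normalization, 2 with the level trend removed and 5 to 6 without single libraries. The maternal-effect list reversed its camera direction with quantile normalization (median log2 fold change -0.038 against WT and -0.105 against MZ) and with the level trend removed (-0.017 and -0.079), while its medians stayed negative; the cause was not tested.

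Of the single genes, only some that had not passed reversed. With quantile normalization Gdf9 went to 0 (MG against WT), -0.092 (MZ against WT) and 0.092 (MG against MZ), Zp3 to 0.22 (MG against WT) and 0.12 (MG against MZ), and Mtor to -0.13 (MG against MZ). With the same FPKM sum, which moved the median of all genes to 0.36 and 0.39 for MG against WT and MZ, Zp3 went to 0.061 for MG against WT. Without single libraries Zp3 ran from -0.61 (without MG 1) to 0.055 (without MG 3) for MG against WT. Mtor for MG against MZ went to -0.048, -0.025 and -0.062 without MG 2, MZ 2 or MZ 3, and to 0.18 without MZ 1; the cause was not tested. Of 39 calls of named genes 38 held with median ratio scaling, 34 with upper quartile scaling, 26 with quantile normalization, 27 with the same FPKM sum, 1 with treat, and 4 (without WT 3) to 28 (without MG 1) when single libraries were left out. None of the 39 reversed. At the depth of these libraries (579000 to 1040900 fragments) a gene under a few FPKM rests on few fragments, and a 2-fold change was seldom recovered in simulation (8 of 99 genes for MG against WT).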

Other observations

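The genes and lists below were picked after their values were seen. In fry's test of change in either direction, which does not compare a list with other genes, 24 of 30 lists passed for MG against WT, 23 for MG against MZ and 0 for MZ against WT (smallest adjusted p = 4.6e-05, 2.4e-06 and 0.53 by fry, from limma). On balance in one direction 0 passed in each. Oocyte transcription factors are an example of a list with members on both sides. Adjusted over the list alone, 6 of its 26 tested members were lower and 4 higher in MG than in WT, and 0 passed over all genes. Members with negative log2 fold changes included Obox5 (-1.10), Obox2 (-1.02), Obox1 (-1.05) and Pou5f1 (-1.03), which encode homeobox factors, and Figla (-0.69), a factor that drives zona pellucida genes. Stat3 (0.84) and Tbpl2 (1.49), the oocyte paralog of the TATA-binding protein, had positive values. The Obox genes are near-identical copies and can share reads. By q under 0.05, the authors' deposited table has lower values in MG than in WT for 3 genes of this list and a higher value for 1.

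Spindle, kinetochore and cytokinesis genes had an unadjusted p under 0.05 as lower for 18 and as higher for 6 of 98 tested members in MG against WT (camera adjusted p = 0.16, median -0.07). Adjusted over the list alone 3 were lower, and Nusap1 passed over all genes. By q under 0.05, the authors' deposited table has 8 of these genes lower and 1 higher in MG than in WT, and 18 lower and 6 higher in MG than in MZ. Hsph1 averaged 40.4 ± 6.90 FPKM in MZ (SD, n = 3), a level between those of WT and MG, and did not pass for MZ against WT.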
